A study of Mus musculus with 7 samples.

How the data were processed

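Omni-ATAC-seq was done on Lgr5-GFP intestinal stem cells from recipients of syngeneic (Syn, 3 libraries) and allogeneic (Allo, 4 libraries) marrow, 7 days after transplantation, in female mice of 8 to 12 weeks. Per the labels' protocols, each library is an independent pool of 3 to 4 mice with 50000 sorted cells, sequenced in pairs of 150 nt. Groups were taken from the titles of the samples.

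The submitters' processing notes name Trim Galore, Bowtie2, MACS2, MACS3 and the mm10 build, without versions or the role of each. The authors deposited 1 list of peaks per library in a 10-column format without header, called per library and not on pooled samples. The authors' values per peak are a score, a fold over background, the −log10 of the p-value and the −log10 of the q-value, and the summit position. They belong to each peak and were used only to rank or filter within a list. The peak-calling threshold is not given in the sources used here, and the lowest −log10 q in the deposited lists was 1.30. How reads were shifted, filtered or extended is not given either, which bears on peak widths and on pileups. Read counts are not used here, so depth is unknown. The deposited fold and −log10 p of each peak were solved for a whole pileup and an expected pileup, within 0.001 in −log10 p for 100% of peaks, and the lowest expected pileup of a library served as its background pileup.

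Peaks on chromosomes 1 to 19 and X were kept. Peaks of all libraries that overlapped by at least 1 bp were merged into regions, and a library held a region if any of its peaks fell in it. Genes came from a RefSeq table of assembly GRCm38.p6, the same build as mm10, with 21631 protein-coding genes and 451 of 456 list entries matched. The table gives no strand, so the planned promoter, 1 kb around the transcription start, was replaced by 1 kb around either gene end. A region or peak was assigned to the gene whose body holds its summit, otherwise to the nearest protein-coding gene within 50 kb. The planned search for sequence motifs was not run, since a genome sequence was not used here.

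Single values per library were compared by exact permutation over the 35 relabellings, two-sided for differences of means and one-sided for the Jaccard index, with a smallest p of 0.0286. Counts of separating regions and genes were set against the same 35 splits. The 26 gene lists were fixed before the data were examined. Their peaks per 10000 peaks were tested by exact permutation, and their share of Allo-only against Syn-only regions by two-sided Fisher's exact test, both with Benjamini-Hochberg adjustment at 0.05. Each of these region sets was also compared with the other merged regions by the same Fisher's exact test, which was planned. As planned, log2 odds ratios with 0.5 added to each count were set against the 35 splits. The Fisher p was set against the splits in addition, which was decided after the log odds counts had been seen. Named items followed a rule set before the data were examined: 5 genes always reported, the 15 best ranked regions per direction, up to 6 list genes per list and direction, and up to 10 gene ends per direction. Not every item that this rule allows is printed, and some are not reported here.

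Alternatives were a −log10 q of at least 5, lists cut to the shortest length of 62977 peaks, windows of 501 bp around summits, coverage of 50% of a region, windows of 500 bp at gene ends, assignment at gene ends only, a block by replicate number and leaving out each library. Leaving out Allo 1 and 2 or Allo 3 and 4, and 2 thresholds, were chosen after seeing the data. On simulated regions with 200 planted in each direction, 200 Allo-only and 200 Syn-only regions were recovered. The planted regions held the full pattern of a group, so this checks only the merging and counting. With none planted and presence shuffled over the libraries region by region, 353 of 103809 regions separated the groups. Shuffling evens out list lengths and the likeness of libraries, so 353 is no background level for the real lists. No 2 lists were copies, the closest pair having a Jaccard index of 0.771. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.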

Results

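Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in intestinal stem cells of mice that had received a bone marrow transplant after lethal irradiation. Lgr5 marks the stem cells at the base of the intestinal crypt, and the recipients carried a GFP reporter of Lgr5 by which these cells were sorted 7 days after transplantation. Syngeneic recipients (Syn, 3 libraries) served as controls, and allogeneic recipients (Allo, 4 libraries) received marrow from BALB/c donors. Such a mismatch can lead to graft-versus-host disease, the attack of donor T cells on recipient tissue. Each library came from 50000 sorted cells pooled from 3 to 4 female mice. The question was how open chromatin of the stem cells differed between the recipient types.

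The measurements were 1 list of peaks per library. On chromosomes 1 to 19 and X, the Syn lists held 71925, 73668 and 76438 peaks and the Allo lists held 62977, 76091, 88861 and 81719. The number of reads behind each list is unknown. A stand-in for depth is the background pileup, the lowest expected pileup that solves the peaks' fold and p-value together, which a different read extension would also move. It was 4.97 ± 0.34 in the Syn libraries (SD, n = 3) and 3.81 ± 0.76 in the Allo libraries (SD, n = 4), and each Allo library lay below each Syn library (two-sided exact permutation p = 0.0857). The median pileup at summits was 39.75 ± 1.26 in Allo (SD, n = 4) and 45.3 ± 1.155 in Syn (SD, n = 3), again lower in each Allo library (exact permutation p = 0.0286). Allo 3 and Allo 4, which held the most peaks, had the lowest background, 3.28 and 3.05, and their peaks are named by another scheme than those of the other 5 libraries, and whether all 7 were called alike is not given in the sources used here.

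The amount of open chromatin called did not separate the recipient types. Allo libraries held 77412 ± 10951 peaks (SD, n = 4) and Syn libraries 74010 ± 2276 (SD, n = 3), a difference of 3402 (two-sided exact permutation p = 0.657). The difference turned to -4476 without Allo 3 and 4 and to -415 without Allo 3 alone. It rose to 8213 without Allo 1 (exact permutation p = 0.2) and to 11279.7 without Allo 1 and 2 (exact permutation p = 0.1). Peaks covered 45.9 ± 7.47 Mb in Allo (SD, n = 4) and 46.5 ± 1.53 Mb in Syn (SD, n = 3; exact permutation p = 0.886). The mean peak was narrower in each Allo library than in each Syn library, 592 ± 17.3 bp (SD, n = 4) against 628 ± 9.18 bp (SD, n = 3; exact permutation p = 0.0571). The share of peaks within 1 kb of either end of a protein-coding gene was 20.3% ± 2.09 in Allo (SD, n = 4) and 20.8% ± 0.36 in Syn (SD, n = 3; exact permutation p = 0.714). This difference changed sign without Allo 3, to 0.26 percentage points, and without Allo 3 and 4, to 0.997 percentage points. It was -1.39 without Allo 1 and -1.91 without Allo 1 and 2 (exact permutation p = 0.1 in both, the smallest possible there).

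Genes that define the sorted cells were open in both recipient types. Regions assigned to Lgr5 (chromosome 10, 115450314 to 115587780, mm10) numbered 7 in each Syn library and 6, 7, 9 and 7 in Allo 1 to 4 (exact permutation p = 1 for n = 3 and 4). Olfm4, a stem cell marker on chromosome 14 (80000302 to 80023141), had 8, 8 and 9 regions in Syn and 6, 7, 11 and 9 in Allo. Ascl2, a transcription factor of the stem cell state on chromosome 7 (142966822 to 142969264), had 5, 5 and 4 regions in Syn and 4, 4, 5 and 4 in Allo. All 3 genes had a gene-end peak in all 7 libraries. Over the 20 genes of the intestinal stem cell list the density was 30.6 ± 1.40 peaks per 10000 peaks in Allo (SD, n = 4) and 31.5 ± 0.61 in Syn (SD, n = 3; exact permutation p = 0.314). Of markers of leukocytes, Ptprc, which encodes CD45, had 2 regions in each Syn library and 1, 2, 5 and 3 in Allo, and Cd3e, a subunit of the T-cell receptor complex, had the same count of 1 in all 7 libraries. Neither had a gene-end peak in any library.

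The overlap of open sequence within and between recipient types did not differ past the threshold. The mean Jaccard index in base pairs was 0.714 within and 0.687 between types, a difference of 0.0269 that missed the threshold (one-sided exact permutation p = 0.0571, 35 relabellings, n = 3 and 4). The Syn libraries overlapped most closely, with a mean of 0.766. The index of Allo 1 with Allo 2 was 0.709 and that of Allo 3 with Allo 4 was 0.742, while these 2 pairs overlapped each other by a mean of 0.670, less than either overlapped the Syn libraries. Syn libraries overlapped Allo 1 and 2 by 0.692 and Allo 3 and 4 by 0.682. The difference was 0.0591 without Allo 3 and 4 and 0.0774 without Allo 1 and 2, each with an exact permutation p of 0.1, the smallest that the 5 libraries left allow, and between 0.0116 and 0.0129 when any 1 Syn library was left out (exact permutation p = 0.267).

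A small part of the open regions separated the recipient types in full. Of 103809 merged regions, 50324 (48.5%) held a peak in all 7 libraries, 1183 were open in the 4 Allo libraries and in no Syn library (Allo-only), and 1051 were open in the 3 Syn libraries and in no Allo library (Syn-only). The total of 2234 regions, 2.15% of all, was larger than in each of the other 34 ways of dividing the 7 libraries into 4 and 3, of which the highest gave 1701 (exact permutation p = 0.0286, the smallest p that n = 3 and 4 allow). Allo-only regions had a median width of 497 bp and a median within-library rank percentile of 27.9, against 403 bp and 17.3 for Syn-only regions and 889 bp and 65.5 for regions open in all libraries. Gene ends held 4.82% of Allo-only, 3.90% of Syn-only and 26.5% of shared regions. Allo-only regions numbered 2453 without Allo 1 and 1918 without Allo 2, and Syn-only regions 2021 without Allo 2, 1785 without Syn 1 and 1616 without Syn 2. The total was 4351 without Allo 3 and 4, 9296 without Allo 1 and 2, 3537 without Allo 1, 3939 without Allo 2 and 1167 when regions had to pass a stricter threshold where present. When any Syn library was left out, 2 of 15 splits gave as many regions, and the highest other split gave between 4466 and 4724. That split set Allo 3 and 4 against the rest, a division that no split into 4 and 3 holds.

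**Figure D1:**
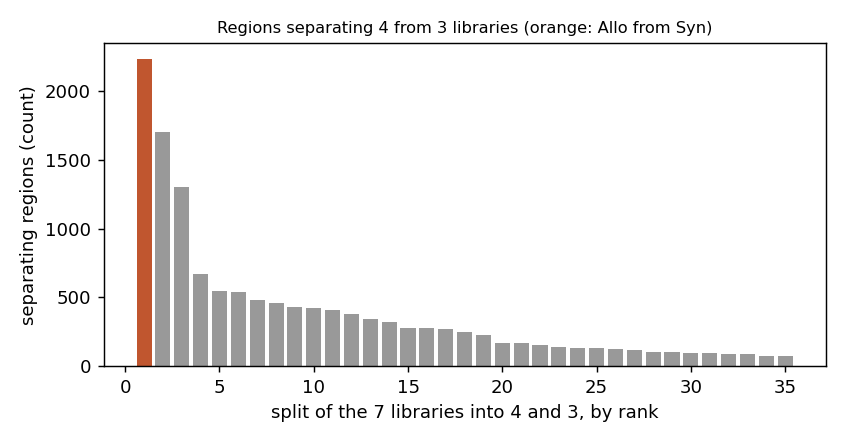
Number of regions (vertical axis, count) open in all libraries of 1 side and none of the other, for each of the 35 splits of the 7 libraries into 4 and 3, ordered by rank along the horizontal axis. The orange bar is Allo against Syn with 2234 regions, and the highest grey bar stands at 1701.

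The highest ranked Allo-only regions lay at or near genes of several functions. The first was at the end of Apol10b on chromosome 15 (77598184 to 77599060, rank percentile 82.9), followed by regions in the bodies of Gtpbp4 on chromosome 13 (8984712 to 8985734, rank percentile 78.7) and Pnpla7 on chromosome 2 (25028876 to 25029993, rank percentile 76.3). The others of the first 15 were at or near Crisp2, Agfg1, Garnl3, Muc5ac, Prpf38b, Cnot10 and Tram1, at or near the interferon-inducible GTPase genes Gvin1 and Gbp4, the transcription factor gene Batf2 and the interleukin 7 gene Il7, and at chromosome 9, 30555018 to 30555728, with no protein-coding gene within 50 kb. The first Syn-only region, on chromosome 1 (94208659 to 94209357, rank percentile 67.1), also had no gene within 50 kb, as had 4 others of the first 15. Those with a gene included regions at or near Usp26, Nox3, Gm44812, St7, Rad51b, Cdkal1, Usp34, Bach1 and Ptprq. Rank percentiles above 50 were found for 82 Allo-only and 7 Syn-only regions (Fisher's exact test p = 3.26e-16), and 9 of the 35 splits gave a contrast as large.

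Interferon-response genes were the 1 list of 26 that passed the test between Allo-only and Syn-only regions. They held 16 of 1183 Allo-only regions and 1 of 1051 Syn-only regions (odds ratio 14.4, two-sided Fisher's exact test p = 3.64e-04, Benjamini-Hochberg adjusted p = 0.00947 over 26 lists). These are shares of 1.35% and 0.0951%, against 0.162% of all merged regions. Compared with the other merged regions, the odds ratio was 9.24 for Allo-only regions (Fisher's exact test, adjusted p = 3.49e-09). For Syn-only regions it was 0.585, which rests on 1 region. The Allo-only regions belonged to 11 of the 33 list genes with any region. They included Gbp4 at its gene end (chromosome 5, 105139077 to 105140109, rank percentile 63.0), Iigp1, an immunity-related GTPase (chromosome 18, 60366156 to 60366865, rank percentile 54.4), Cd274, which encodes the checkpoint ligand PD-L1 (chromosome 19, 29376394 to 29376748, rank percentile 53.6), and Irf9, a subunit of the interferon-activated factor ISGF3 (chromosome 14, 55612700 to 55613167, rank percentile 47.7). Tgtp1 and Socs1, a feedback inhibitor of cytokine signalling, were also among them, and the Syn-only region lay in Irgm1. Regions are not independent replicates, and the splits of the libraries did not settle the list: by the planned log2 odds ratio (3.31, with 0.5 added to each count) 12 of the 35 splits lay as far from 0, but 9 of the other 11 held no region of the list, so that set sizes and the added 0.5 fixed their values. By the Fisher p, a measure added after the log odds were seen, only the real split reached this value (lowest p of another split 0.0556), but no other split held more than 4 list regions. By the same Fisher's exact test, the call was lost under the stricter threshold (adjusted p = 0.225), with lists of matched length (adjusted p = 0.111), with summit windows (adjusted p = 0.128), at gene ends alone (adjusted p = 1), without Allo 1 (adjusted p = 0.197), without Allo 1 and 2 (adjusted p = 0.0979) and with 2 thresholds (adjusted p = 0.137), while Allo-only regions stayed ahead in each. By the same exact test it was kept without any 1 of the other 6 libraries (adjusted p between 9.95e-04 and 0.0170) and without Allo 3 and 4, within 1 naming scheme (21 of 1581 against 2 of 2770 regions, adjusted p = 1.52e-06).

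Measured as density, peaks assigned to interferon-response genes numbered 17.1 ± 0.87 per 10000 peaks in Allo (SD, n = 4) and 13.4 ± 0.18 in Syn (SD, n = 3), a ratio of 1.28 and higher in 4 of 4 Allo libraries than in any Syn library. MHC class II genes, which encode the antigen-presentation complex, had 5.51 ± 0.20 in Allo (SD, n = 4) and 4.55 ± 0.09 in Syn (SD, n = 3), a ratio of 1.21. Both had an exact permutation p of 0.0286, the smallest possible, and an adjusted p of 0.297, so that 0 of 26 lists passed the correction and 2 had an unadjusted p under 0.05. With n = 3 and 4, 15 lists at the smallest p would have been needed for any to pass. With peaks at gene ends only, where fewer peaks are counted, the difference fell from 3.75 to 1.14 for interferon response (exact permutation p = 0.0571) and from 0.955 to 0.23 for MHC class II (exact permutation p = 0.0857). With lists of matched length the differences were 3.57 for interferon response and 0.516 for class II (unadjusted exact permutation p = 0.0286 in both). Markers of tuft cells, a chemosensory cell type, had 10.02 ± 1.17 in Allo (SD, n = 4) and 7.57 ± 0.44 in Syn (SD, n = 3), and markers of T and NK cells had 7.14 ± 0.65 and 6.13 ± 0.11, each higher in 4 of 4 Allo libraries (exact permutation p = 0.0571, adjusted p = 0.297). Enteroendocrine markers gave 5.89 ± 0.49 and 5.13 ± 0.47 with the same p-values (exact permutation).

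**Figure D2:**
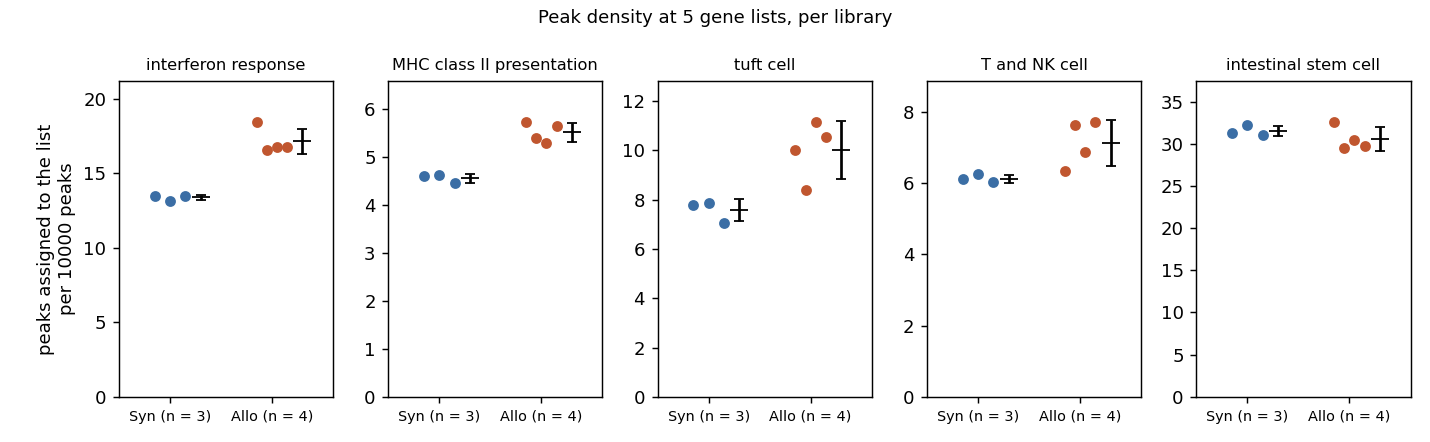
Peaks assigned to 5 gene lists per 10000 peaks (vertical axis) in each library of the Syn and Allo groups (horizontal axis), with 1 point per library and a black mark for mean ± SD. For interferon response the Allo libraries lie between 16.6 and 18.4 and the Syn libraries between 13.2 and 13.5, and for stem cell genes the groups overlap.

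The ratio of Allo to Syn density lay between 0.927 and 1.13 for the other 21 lists, with no unadjusted exact permutation p under 0.05. It was 1.13 for B cell, 1.11 for pan-haematopoietic, 0.988 for myeloid, and 1.06 for endothelial and stromal markers. Among epithelial lists it was 0.970 for stem cell, 1.02 for Wnt, 1.06 for Notch, 1.02 for epithelial identity, 0.929 for absorptive enterocyte, 1.09 for Paneth and 1.03 for goblet cell genes. For stress and damage programs it was 0.983 for NF-kB and STAT3 inflammation, 0.990 for cell death, 0.974 for p53 response, 0.927 for regeneration and YAP, 0.991 for immediate early AP-1 and 1.11 for unfolded protein response. The ratio was 1.04 for MHC class I, 0.973 for cell cycle, 0.943 for mitochondrial respiration and 0.980 for chromatin-modifying enzymes.

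Among single list genes, no list apart from interferon response passed between the region sets. MHC class II genes had 3 Allo-only and 0 Syn-only regions, at or near Ciita, the master regulator of the class (chromosome 16, 10495096 to 10495427), H2-Oa and H2-Aa (adjusted Fisher p = 1). Their rank percentiles were 34.7, 31.5 and 3.78. The counts stayed at 3 and 0 under the stricter threshold but were 1 and 1 with lists of matched length. Nlrc5, the corresponding regulator of MHC class I, had 1 Allo-only region (chromosome 8, 94447657 to 94448160). Stem cell genes had Allo-only regions near Sox9 and Cd44 and Syn-only regions near Ephb2 and Rgmb. Wnt genes had Allo-only regions in Tcf7l2 and Syn-only regions at or near Lef1, Fzd5 and Ccnd1. Absorptive enterocyte genes had Syn-only regions at or near Apob, Apoa4, Rbp2 and Mme and an Allo-only region in Mttp. Epithelial identity genes with Allo-only regions at or near them included Epcam, Ehf, Cdh1 and Gata6. The naming rule picked 57 Allo-only and 39 Syn-only regions. Under the stricter threshold 37 and 28 of them still separated the types, and with lists of matched length 34 and 24. Some ranked low, with rank percentiles of 2.64 and 17.3 at Lef1, 5.22 and 35.8 in Tcf7l2 and 11.7 near Rgmb. The regions near Sox9 stood at 48.9 and 48.5.

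Gene ends separated the recipient types for few genes. Of 21631 protein-coding genes, 13113 had a gene-end peak in all 7 libraries. Another 27 had one in all 4 Allo and no Syn libraries, and 15 in all 3 Syn and no Allo libraries. This total of 42 did not stand apart from other divisions of the libraries, since 2 of the 35 splits reached it, the real one included, and the other gave 48 (exact permutation p = 0.0571, n = 3 and 4). The best ranked Allo genes were Cc2d2b, Apol10b, Shisal1, Gbp4, H2-Eb2, Oas2, Serping1, Syce1l, Tgtp1 and Gm4952, of which Gbp4, Oas2 and Tgtp1 are interferon-inducible. The best ranked Syn genes were Ruvbl2, C9, Sec14l3, Klk1b16, Gm1110, Rassf9, Cnga1, Frem2, Cabp2 and Npffr2. At Cc2d2b, Shisal1, Ruvbl2, Gm1110 and Frem2 no merged region separated the types. The balance of Allo to Syn genes was 31 to 29 under the stricter threshold, and it turned to 28 to 34 with lists of matched length, 43 to 47 without Allo 2, 36 to 38 without Syn 2 and 35 to 67 without Allo 3 and 4. The total was 102 without Allo 3 and 4, 209 without Allo 1 and 2, and 64, 74, 72, 71 and 90 without Syn 1, Syn 2, Syn 3, Allo 1 and Allo 2.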

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

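The comparisons over splits of the libraries were planned for separating regions, for gene ends and for the log odds of the lists. Those by Fisher p, by the number of lists called and for rank percentiles were not planned. The tests of depth, labels, preparation and immune cells were chosen after the results were seen, and the outcomes expected under each explanation were all written down after the values, or values close to them, were known.

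In 51 sets of 4 Allo values, 6 had 1 library far from the other 3, where chance gives about 1 in 20. Allo 1 stood highest in interferon-response density (18.4 peaks per 10000), but its list was the shortest. It held 116 interferon-response peaks, against 126, 149 and 137 in Allo 2, 3 and 4. Allo 1 stood lowest in endothelial and stromal density (5.56 per 10000), and lowest in gene-end peaks of tuft cell genes (12 genes) and of stem cell genes (17 genes). Allo 3 stood highest in regions at Ascl2 (5 regions) and in gene-end peaks of myeloid genes (7 genes). Where the other 3 libraries share a whole number, a difference of 1 gene or region is enough to set a library apart.

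The first pattern is the 2234 regions that separate Allo from Syn. Chance division is argued against, since 1 of the 35 splits, the real one, gave as many and the highest other gave 1701, but this rests on all 3 Syn libraries: without any 1 of them, the split of Allo 3 and 4 from the rest gave more than the real one (4466 against 3259, 4608 against 3209 and 4724 against 2959), a split that follows the naming scheme. List length is argued against too, since with matched lists 1 of 35 splits, the real one, gave as many (2140, highest other 1789). Exchanged labels of Allo 3 and 4 are argued against by the shares of regions they hold, which favoured those of Allo 1 and 2 over those of Syn by at least 33.3 percentage points, where no Syn library exceeded -43.8; a difference in preparation of Allo 3 and 4 cannot by itself account for the 4351 regions separating Allo 1 and 2 from Syn within 1 naming scheme (highest other of 10 splits 2014, too few to exclude chance). For the Syn-only part, lower depth of the Allo libraries stays open: the median summit pileup was 39.75 in Allo and 45.3 in Syn (exact permutation p = 0.0286), and shares of weak Syn regions held by Allo 3 and 4 exceeded those of Allo 1 and 2 by at least 1.66 percentage points, within a spread of 13.4. The recipient type stays open as a biological explanation.

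The second pattern is the interferon list. For the number of lists called, a comparison that was not planned, 1 of 35 splits gave as many (1 list, highest other 0). The other splits had fewer regions to test (a median of 238 and at most 1701, against 2234). By the planned log odds 12 of 35 splits lay as far from 0 (3.31, highest other 5.36), but 9 of the other 11 held no region of the list, so that this comparison decides nothing and chance stays open for the list. A difference in preparation of Allo 3 and 4 is argued against, since the lower of Allo 1 and 2 had a density of 16.56 and the highest Syn library 13.49. Immune cells in the sorted Allo fraction cannot be excluded: 36 T, NK and pan-haematopoietic marker genes gained a mean of 0.667 gene-end peaks in Allo against 5 over 35 interferon genes, and the exact permutation p of the difference in gain was 0.0571; T and NK genes alone gained 1.08, myeloid genes gained 0.917 and the pan-haematopoietic difference was -0.417. Cd3d, Cd3g, Cd8a and Cd4 had 0 assigned regions in all libraries, although a peak reached a gene end of Cd4 in all 7, and Lck had 2 regions in each Syn library and in Allo 1 and 2 and 3 in Allo 3 and 4. An interferon response of the stem cells in allogeneic recipients is therefore a hypothesis that these lists leave open.

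The third pattern is the 3841 regions shared by Allo 3 and Allo 4 alone, against 793 for the next pair. The higher background pileup of Allo 3 and 4 was 3.28 and the lowest of the others 4.46, but an unknown difference in read extension would move it too, so that deeper sequencing stays open. A difference in preparation and a difference between the mice cannot be told apart, because 0 Syn libraries share the naming scheme of Allo 3 and 4. For gene ends, 2 of 35 splits gave as many separating genes (42, highest other 48), so that chance was not excluded.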

How the results depend on the processing

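Leaving out pairs of Allo libraries and the 2 thresholds were chosen after seeing the data. Without Allo 3 and 4, Syn-only regions numbered 2770, all separating regions 4351 and gene ends 102, and the differences in peak number and gene-end share reversed to -4476 and 0.997 percentage points. Without Allo 1 and 2 there were 7040 Allo-only, 2256 Syn-only and 9296 separating regions, 209 gene ends and 0 lists called. With 2 thresholds there were 660, 507 and 1167 regions and 0 lists. Lists called were also 0 under the stricter threshold, matched length, summit windows and gene ends only. Leaving out libraries makes full separation easier, which raises counts of separating regions and gene ends by construction. That does not apply to the 2 thresholds, which leave out no library, or to the lists called. Nor does it account for 7040 Allo-only regions without Allo 1 and 2 against 1581 without Allo 3 and 4. Both settings leave 2 Allo and 3 Syn libraries. Without Allo 1 and 2, recipient type and naming scheme cannot be told apart. Other causes were not tested. Leaving out 1 library gave 1279 to 2453 Allo-only, 1084 to 2021 Syn-only and 2682 to 3939 separating regions, 53 to 90 gene ends, 0 to 1 lists, differences in peak number of -414.67 to 8213.33 and in gene-end share of -1.391 to 0.26 percentage points, and Jaccard differences of 0.0116 to 0.0462. The Allo-only share of separating regions was 52.95%, 44.8% with matched lists, 43.7% at 50% coverage, 36.3% without Allo 3 and 4 and 75.7% without Allo 1 and 2. The interferon density stayed higher in Allo in all alternatives, by 1.14 at gene ends only and by 3.32 to 3.94 when 1 library was left out, where the design allows no p below 0.0667 or 0.1. Replicate numbers did not pair the libraries (correlations of -0.0174, -0.0025 and -0.026), and a replicate block gave 1966 for peak number, -0.207 for gene-end share, 2691 regions (1358 Allo-only, 1333 Syn-only), 54 gene ends and 0 lists by density. The motif alternatives were not run. Weak regions are limited by the unknown depth.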

Other observations

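The test of regions at Allo 3 and 4 was chosen after their number was seen. Compared with 5725 regions held by exactly 2 libraries of other pairs, the 3841 regions of Allo 3 and 4 alone were counted more often at tuft cell genes (11 against 3, odds ratio 5.48), at Paneth cell genes (6 against 0) and at Wnt genes (16 against 8, odds ratio 2.99), and less often at absorptive enterocyte genes (3 against 17) and at NF-kB and STAT3 inflammation genes (0 against 7). By Fisher's exact test over 26 lists, 0 passed the correction, with adjusted p of 0.0621 for tuft and for Paneth cell genes and 0.0962 for Wnt, 0.143 for absorptive enterocyte and 0.243 for inflammation genes, and these 5 had an unadjusted p under 0.05. By the same exact test, interferon-response genes held 15 of these regions against 13 (odds ratio 1.72, adjusted p = 0.510).

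Peaks at gene ends were counted for 9 lists after the data were seen. Of 35 interferon-response genes, Allo libraries had such a peak at 31 to 33 and Syn libraries at 26 to 28, a mean difference of 5 (two-sided exact permutation p = 0.0286, n = 3 and 4, unadjusted), and 2 of them had one in all Allo and no Syn libraries. All 13 MHC class I genes had such a peak in each library, so that no gain could be seen, and each library had one at 6 of 8 class II genes. Tuft cell genes had 12.8 ± 0.50 of 15 in Allo (SD, n = 4) and 11.7 ± 0.58 in Syn (SD, n = 3; exact permutation p = 0.114).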
